A study of Arabidopsis thaliana with 2 samples.

How the data were processed

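Small RNA was sequenced on the Solexa platform, per the labels, from 1 control library and 1 low-oxygen library of whole Arabidopsis roots. The labels do not state how long the low-oxygen treatment lasted. The authors deposited, for each library, a list of distinct sequences with their read counts; these are whole-number counts with no normalization. Adapter trimming, aligner and genome build used by the authors are not given in the sources used here. The shortest deposited read had 18 nt and the longest 36 nt, and 80.0% of distinct control sequences and 80.8% of distinct low-oxygen sequences were read once. A further deposited list for the whole series gave sequences with identifiers and lengths and was not used.

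Every distinct sequence was matched end to end, without mismatch, to both strands of RefSeq TAIR10.1, and all coordinates come from these matches. A sequence took 1 class by priority: 1 repeated base (80% or more of its bases), rRNA (nuclear units extended 3600 nt past 5.8S, 5S repeats and organelle rRNA), tRNA with spliced forms and CCA tails, snRNA or snoRNA, miRNA hairpin, TAS locus, other organelle sequence, protein-coding exon in sense, pseudogene, other parts of protein-coding genes, other noncoding genes, between genes, and no match. Mature miRNAs were those of the reference, 428 in all, counted by exact sequence and summed by family. miR8175, which matched tRNA (6 and 88 reads), was left out.

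Ratios compare RPM, the count scaled to the deposited reads of the library. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the 2 counts, and intervals of shares are exact binomial. PCR copies are not independent molecules, so these cover counting error only. A count of 0 allows up to 3 counts, which is 1.63 RPM in control and 1.80 in low oxygen. Families with 20 or more reads, windows of 500 bp with 50 or more reads of 20 to 24 nt (each read divided over its matches) and mRNAs from sense exon reads were compared; fractional counts were rounded for intervals. Medians of gene lists were placed among 10000 random lists matched on reads. Length-scaled ratios, added after the data were seen, divide by the rRNA ratio of each read length from 18 to 28 nt and assume that rRNA fragments themselves did not differ.

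The text names the 10 most abundant families, families with 100 or more reads and a size call (at most 12 each way), every family of lists with 4 or fewer members, the 5 largest ratios each way among genome-matched sequences and windows with 200 or more reads, all TAS loci, the 6 hypoxia genes with the most reads and 3 genes of each other mRNA list. This rule and the lists were fixed before the data were examined. Alternatives were other scalings (reads outside structural RNA, miRNA reads, a trimmed mean of log ratios over 19196 shared sequences, matched 20 to 24 nt reads), other read minimums and thresholds, hairpin reads, 21-nt or single-match reads, and distinct sequences.

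The methods were tested on simulated data. All 300 planted sequences were found at their place and 0 of 300 with 1 base exchanged. For control against low oxygen, over 11066 simulated sequences, 96.3% of intervals held the true ratio. Of 50 sequences per fold size, 22% were called at 1.5-fold, 68% at 2-fold, 76% at 3-fold and 100% at 5-fold. The 1.5-fold and 3-fold changes were all decreases and the 2-fold and 5-fold changes all increases. Direction and fold size were thus not separated. Of 10866 unchanged sequences, 2.79% were called. Both simulated libraries had counting error only and no length shift, so this is not a false-call rate for the real libraries. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.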

Results

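Small RNAs of whole roots of Arabidopsis thaliana (accession Col-0, aged 2.5 weeks) were sequenced from 2 libraries, 1 from control roots and 1 from roots kept in 0.1% oxygen. The series asks which small RNAs respond to low oxygen. The control library held 1837699 reads in 383969 distinct sequences and the low-oxygen library 1666532 reads in 390392 distinct sequences, all of 18 to 36 nt. Of the distinct sequences, 75599 were present in both libraries. With 1 library per condition, no difference had a replicate check, no test between conditions was possible, and every interval is a 95% interval that covers counting error only. Ratios are low oxygen over control, in RPM (the read count scaled to the library's deposited total), and a size call required a ratio of at least 1.5 either way with an interval excluding 1.

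The length profile of the low-oxygen library was shifted to shorter reads. Reads of 21 nt, the usual length of miRNAs, made up 12.1% of the control library (exact binomial interval 12.02 to 12.12) and 17.6% of the low-oxygen library (17.6 to 17.7). Reads of 24 nt, the usual length of heterochromatic siRNAs, made up 19.8% (19.7 to 19.9) and 17.5% (17.4 to 17.5). Reads of 25 to 29 nt took 33.8% of the control library and 9.69% of the low-oxygen library, and reads of 18 to 20 nt took 10.4% and 25.1%. The longest reads went the other way, from 1.41% to 2.18% at 35 nt and from 2.50% to 3.76% at 36 nt. Among genome-matched reads outside structural RNA (rRNA, tRNA, snRNA and snoRNA), 21-nt reads stood at 32.6% and 38.0% and 24-nt reads at 45.7% and 37.1%. Outside structural RNA, reads of 35 nt numbered 25836 in control and 36256 in low oxygen, and those of 36 nt 45978 and 62627. Leaving out sequences of 1 repeated base, 0 and 0 of the former and 1 and 0 of the latter matched the genome. The rise at 35 and 36 nt is thus not one of genome-matched RNA outside these classes.

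**Figure D1:**
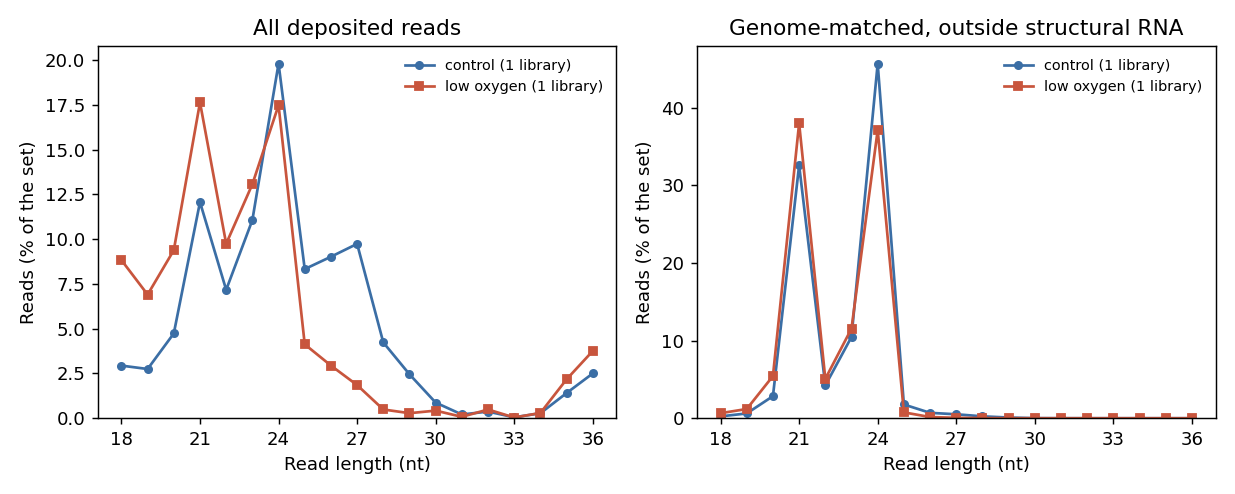
Share of reads (percent of the set, y axis) at each read length (nt, x axis) in the control and low-oxygen libraries, for all deposited reads and for genome-matched reads outside structural RNA. The share of 24-nt reads in the second set was 45.7% in control and 37.1% in low oxygen, and that of 21-nt reads 32.6% and 38.0%.

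The shift was shared by RNA classes of unlike origin. Ribosomal RNA fragments had a ratio of 2.90 (interval 2.87 to 2.93) at 18 nt, 1.56 (1.54 to 1.57) at 21 nt, 0.778 (0.771 to 0.784) at 24 nt and 0.186 (0.183 to 0.188) at 27 nt. Sense fragments of protein-coding exons had ratios of 3.43 at 18 nt, 1.90 at 21 nt, 0.964 at 24 nt and 0.139 at 27 nt. A ratio scaled by rRNA reads of the same length, an alternative chosen after the data were seen, is therefore given beside the ratios of most small RNAs named below and is called the length-scaled ratio. At 21 nt other classes lay up to 1.76 times above rRNA (tRNA fragments), so length-scaled ratios carry that spread between classes beyond their counting intervals.

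**Figure D2:**
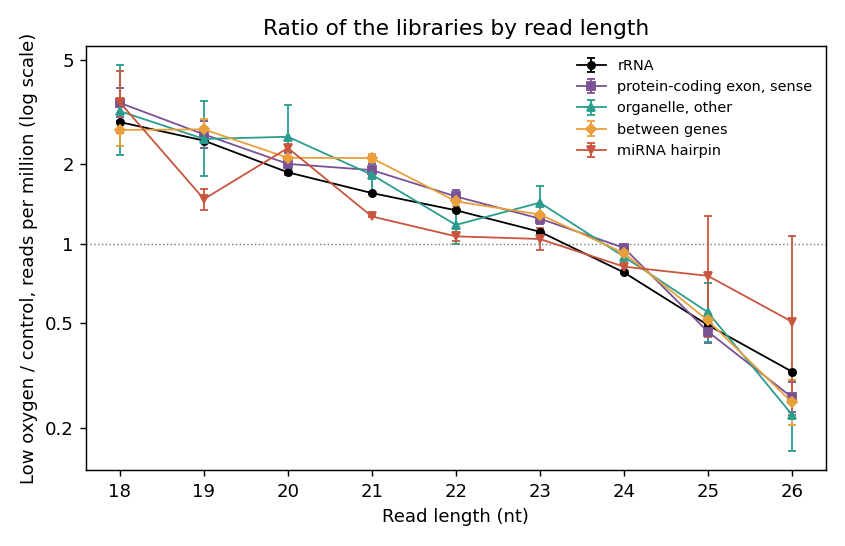
Ratio of RPM, low oxygen over control (log scale, y axis), at each read length (nt, x axis) for 5 classes of reads, with 95% counting intervals as bars. In the rRNA class the ratio went from 2.90 at 18 nt to 0.778 at 24 nt.

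By class, rRNA fragments were the largest share of both libraries, at 56.2% of control reads (56.1 to 56.3) and 50.1% of low-oxygen reads (50.02 to 50.18). Reads within annotated miRNA hairpins took 7.34% (7.31 to 7.38) and 9.65% (9.61 to 9.70). Reads at TAS loci, whose transcripts are processed into trans-acting siRNAs, took 0.124% and 0.272%. Transfer RNA fragments took 1.36% and 1.41%, sense fragments of protein-coding exons 1.34% and 1.48%, and reads between annotated genes 8.09% and 8.38%. A perfect genome match was found for 79.4% of control reads and 77.1% of low-oxygen reads. Reads made of 1 repeated base took 0.379% and 1.20%.

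Most measured miRNA families had a higher RPM in the low-oxygen library. Of 215 annotated families, 73 had a read and 37 had 20 or more reads over both libraries; the ratio was above 1 in 32 of the 37 and below 1 in 5. The size call held for 14 families higher and 1 lower in the low-oxygen library. The median family ratio was 1.65, a log2 ratio of 0.72, so single families are to be read against that shift. After length scaling the median log2 ratio was 0.14, 20 families lay above 1 and 17 below it, and 5 of the 14 families kept a call of higher.

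The families that kept the call were miR172, miR158, miR161, miR391 and miR5026. miR172, which targets AP2-type transcription factors, had 11.4 RPM in control and 58.8 in low oxygen, a ratio of 5.15 (3.19 to 8.68) and a length-scaled ratio of 3.30 (2.05 to 5.58). Of its 21 control and 98 low-oxygen reads, 15 and 93 were of the miR172a sequence, so the family's higher value rests on that sequence. miR158 had 1340 RPM in control and 4831 in low oxygen, a ratio of 3.60 (3.45 to 3.77) and a length-scaled ratio of 1.93 (1.85 to 2.02). miR161, which targets pentatricopeptide repeat (PPR) genes, had a ratio of 3.44 (2.55 to 4.69) and 2.21 (1.64 to 3.01) after length scaling, but 1.69 when all 20 to 24 nt reads of its hairpins were counted. miR391 had 3.48 (2.21 to 5.63) and 2.23 (1.42 to 3.62). miR5026, named after its values were seen, had 4 control and 53 low-oxygen reads, a ratio of 14.6 (5.38 to 55.6) and a length-scaled ratio of 9.38 (3.46 to 35.7).

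Further families passed the size call on deposited reads and fell short of 1.5 after length scaling. miR157 had a ratio of 2.30 (2.21 to 2.38) and a length-scaled ratio of 1.47 (1.42 to 1.53). miR390 had 2.08 (1.96 to 2.21) and 1.34 (1.26 to 1.42), miR173 had 1.95 (1.64 to 2.31) and 1.45 (1.23 to 1.73), and miR159 had 2.31 (1.77 to 3.03) and 1.48 (1.14 to 1.95). miR408 had a ratio of 1.65 (1.43 to 1.90) and a length-scaled ratio of 1.06 (0.921 to 1.22). Its 2 strands differed: miR408-5p had 209 and 362 reads, a ratio of 1.91 (1.61 to 2.28). The miR408-3p sequence had 125 and 138 reads, a ratio of 1.22 (0.949 to 1.56), which falls short of the size call. The direction of miR156, which targets SPL transcription factors, depended on the scaling, with a ratio of 1.65 (1.59 to 1.71) and a length-scaled ratio of 0.924 (0.892 to 0.958). The single family called lower was miR5653, also named after its values were seen, with 32 control and 10 low-oxygen reads and a ratio of 0.345 (0.151 to 0.718). After length scaling it was called lower with miR162 and miR169, at 0.534 (0.306 to 0.917) and 0.497 (0.367 to 0.670).

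The most abundant family, miR166, which targets class III HD-ZIP transcription factors, held 64.8% of mature miRNA reads in control and 57.7% in low oxygen. Its ratio was 1.18 (1.16 to 1.19), and 0.755 (0.747 to 0.762) after length scaling; miR165 had 1.16 (1.13 to 1.18) and 0.744 (0.727 to 0.761). miR168, which targets AGO1, had 1.44 (1.401 to 1.488) and 0.927 (0.900 to 0.956). miR164 had 1.45 (1.38 to 1.52) and 0.932 (0.887 to 0.979), and miR167 had 1.32 (1.23 to 1.41) and 0.852 (0.794 to 0.913). miR829, read mainly as a 24-nt sequence, went the other way, with 0.867 (0.804 to 0.934) and 1.11 (1.03 to 1.20). Scaled to miRNA reads, miR166 and miR165 had ratios of 0.891 and 0.878.

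**Figure D3:**
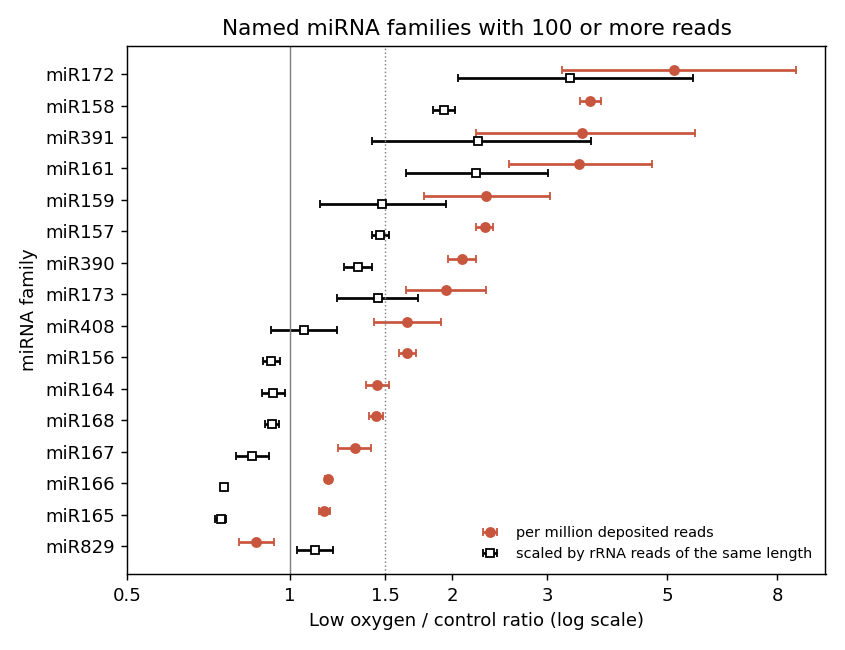
Low oxygen over control ratio (log scale, x axis) of the named miRNA families with 100 or more reads (y axis), scaled to deposited reads (filled circles) and scaled by rRNA reads of the same length (open squares), with 95% counting intervals. The dotted line marks 1.5; miR172 had 5.15 and 3.30, and miR166 had 1.18 and 0.755.

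By list, 4 of the 12 measured families that target developmental transcription factors were called higher and none lower; after length scaling 1 was called higher and 1 lower (miR169). The list's median log2 ratio of 0.52 stood at percentile 30.1 of random family lists matched on reads. Families were counted whichever strand of the hairpin was read. All miR396 reads were of miR396a-3p and miR396b-3p. For miR160, 13 of 14 control and 16 of 18 low-oxygen reads were miR160c-3p, and for miR171, 17 of 18 and 22 of 28 were miR171c-5p. The auxin list (4 measured families, 1 higher and 0 after length scaling) had a median of 0.52 at percentile 31.3. Of the 12 measured families known from Arabidopsis and close relatives, 6 were called higher and 2 after length scaling, with a median of 0.79 at percentile 63.3. Both measured families that start tasiRNA production, miR173 and miR390, were called higher, and neither after length scaling; miR828 had no read. In the small RNA machinery list, miR162 had 37 and 24 reads, a ratio of 0.715 (0.409 to 1.23), and miR403 had 2 and 4 reads. All miR162 reads were of the miR162a-5p sequence, so these values do not measure the other strand of its hairpin. miR400 of the PPR list had 2 and 1 reads. In the copper list, miR398 had 14 and 25 reads, all of the miR398a-5p sequence, a ratio of 1.97 (0.985 to 4.10). Its other strand was therefore not measured, and miR397 and miR857 had no read. In the phosphate and sulfate list, miR399 had a ratio of 0.913 (0.509 to 1.62) and miR827 of 2.21 (0.985 to 5.28), miR395 had 3 and 7 reads, and miR2111 had 4 and 6.

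The TAS loci had a higher RPM of 20 to 24 nt reads in the low-oxygen library. Pooled, they had 1230 RPM in control and 2688 in low oxygen, a ratio of 2.19 (2.08 to 2.30) and a length-scaled ratio of 1.501 (1.427 to 1.579). TAS2 (chromosome 2, 16539384 to 16540417) had a ratio of 3.42 (2.84 to 4.14) and a length-scaled ratio of 2.33 (1.94 to 2.83). TAS1A (chromosome 2, 11721539 to 11722468) had 2.51 (2.29 to 2.76) and 1.65 (1.504 to 1.811), TAS1B (chromosome 1, 18549204 to 18550042) had 2.68 (2.05 to 3.53) and 1.78 (1.36 to 2.34), and TAS1C (chromosome 2, 16537288 to 16538277) had 2.19 (1.93 to 2.49) and 1.83 (1.61 to 2.08). TAS4 (chromosome 3, 9417551 to 9418705) had 2.43 (2.08 to 2.86) and 1.57 (1.34 to 1.84). TAS3A (chromosome 3, 5861491 to 5862437), the locus started by miR390, had 1.64 (1.501 to 1.794) and 1.101 (1.007 to 1.204). TAS3B (chromosome 5, 20134200 to 20134786) had 0 and 3 reads, and TAS3C (chromosome 5, 23394005 to 23394500) had 0 and 1. Reads of 21 nt alone had a pooled ratio of 2.34, and those of TAS1C a ratio of 3.76. In TAS1A, the most used 21-nt register held 93.9% of 21-nt reads in control and 92.0% in low oxygen. In TAS1C it held 44.8% and 64.0%. A single TAS1C sequence, named below, had 31 of the 145 control and 209 of the 494 low-oxygen reads of 21 nt at this locus. In low oxygen it must lie in the most used register, since its 209 reads are more than the 494 leave outside a register holding 64.0%. Whether that register was also the most used one in control was not examined. A change in phasing therefore cannot be told apart from that of this sequence.

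Among 1662 genome windows of 500 bp with 50 or more siRNA reads, the median ratio was 0.989 (1.12 length-scaled), with 105 windows called higher and 105 lower. The 37 windows made mostly of 21 to 22 nt reads had a median ratio of 2.33 (1.55 length-scaled), with 26 higher and 0 lower. Of these, 13 windows, all called higher, lay in the 1 region of chromosome 3 described next, and the 24 outside it had a median of 1.57 (1.19 length-scaled), with 13 higher and 0 lower. The other 1625 windows had a median of 0.981 (1.12 length-scaled), with 79 higher and 105 lower. The balance depended on the scaling: 181 windows were called higher and 44 lower after length scaling, 88 and 151 with a trimmed mean of log ratios, and 53 and 254 when scaled to matched 20 to 24 nt reads.

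Among the 186 windows with 200 or more reads, the 5 with the largest ratios, from 2.86 (2.44 to 3.35) to 3.16 (2.82 to 3.55), lay in 1 region of chromosome 3 (1963501 to 1970500, TAIR10.1). It overlaps the protein-coding genes AT3G06435 and AT3G06436 and 3 noncoding genes, and 76.3% of its 21-base words also occur in it as reverse complement. Over the region, reads of 20 to 24 nt had 2216 RPM in control and 6349 in low oxygen, a ratio of 2.87 (2.76 to 2.97) and a length-scaled ratio of 2.34 (2.25 to 2.42). Reads of 24 nt in it had a ratio of 5.22 (4.87 to 5.59), or 6.71 (6.26 to 7.19) length-scaled, and those of 22 nt 1.89 (1.79 to 1.99), or 1.41 (1.34 to 1.49). The lowest ratios among the 186 were 0.469 (0.344 to 0.634; 0.580 length-scaled) between genes on chromosome 4 (7611501 to 7612000), 0.501 (0.610) on chromosome 5 (14847501 to 14848000, between genes), 0.540 (0.643) at AT4G12420 (chromosome 4, 7353001 to 7353500), 0.551 (0.671) on chromosome 3 (9781001 to 9781500, between genes) and 0.590 (0.703) at AT4G32990 (chromosome 4, 15922501 to 15923000). Of the 187 control and 84.9 low-oxygen reads in the chromosome 5 window, 153 and 51 were of 1 sequence of 24 nt, named below. The low ratio of that window thus rests on this sequence.

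**Figure D4:**
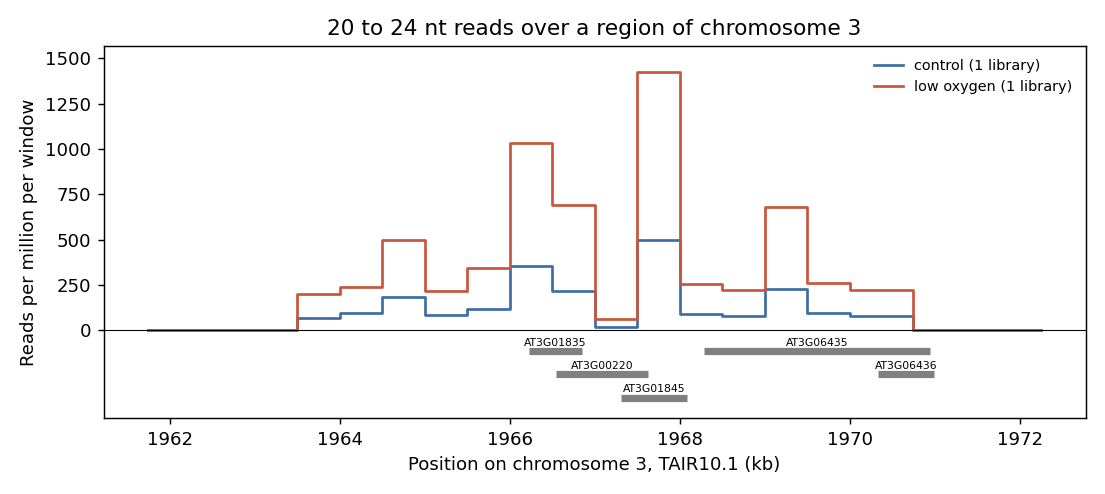
Reads of 20 to 24 nt (RPM per window of 500 bp, y axis) along chromosome 3 (kb, x axis) in both libraries, with annotated genes as grey bars. Over the region the low-oxygen library held 6349 RPM and the control library 2216.

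Of single genome-matched sequences of 18 to 26 nt with 200 or more reads outside structural RNA, the largest ratio was that of a 21-nt sequence on the minus strand of TAS1C, TACAAGCGAATAGACCATTTA (chromosome 2, 16537879 to 16537899), at 7.43 (5.08 to 11.2) and 4.77 after length scaling. The 20-nt miR157d, TGACAGAAGATAGAGAGCAC, which matches 4 places (among them chromosome 1, 18026989 to 18027008), had 5.36 (4.03 to 7.24) and 2.87 after length scaling, and miR158a-3p, TCCCAAATGTAGACAAAGCA (chromosome 3, 3366349 to 3366368), had 3.63 (3.465 to 3.796) and 1.94. The miR157d sequence equals miR157a-5p (4119 and 8409 reads) without its first base, so reads of the 2 sources cannot be told apart. A TAS1A sequence, TGATTGGATCTTAGGAAATTA (chromosome 2, 11721986 to 11722006), had 3.18 (2.50 to 4.07) and 2.04 after length scaling, and an 18-nt sequence between genes that matches 2 places, TCCGCTGTAGCACATCGG (chromosome 2, 12333097 to 12333114), had 3.82 (3.04 to 4.84) and 1.32 after length scaling. The 5 lowest among sequences with 200 or more reads were all of 24 nt, with ratios from 0.310 (0.247 to 0.386), or 0.399 length-scaled, for ACGGGACTGGGTTATATGGTAGGA, which matches 13 places, to 0.482 (0.370 to 0.623), or 0.620 length-scaled, for AGGGACGGATCTATGTACAGGAAA (chromosome 5, 17870832 to 17870855, between genes).

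Sense fragments of mRNAs known to rise in low oxygen were more frequent in the library labelled low oxygen. Of 38 listed hypoxia genes, 26 had a read, 20 with a higher RPM in low oxygen and 6 with a lower one, and 17 were read only in low oxygen. Pooled, they had 21 control and 115 low-oxygen reads, a ratio of 6.04 (3.77 to 10.13). No listed gene reached 20 reads, so counts are given without ratios. HUP54 (AT4G27450) had 0 and 15 reads, ADH1, alcohol dehydrogenase (AT1G77120), 0 and 14, PDC1, pyruvate decarboxylase (AT4G33070), 1 and 12, SUS1, sucrose synthase (AT5G20830), 0 and 10, HRA1 (AT3G10040) 0 and 10, and RBOHD (AT5G47910) 8 and 7. Over the 11 listed genes with 5 or more reads, with zeros set to the floor of 3 counts, the median log2 ratio was 1.88, above that of each of 10000 random gene lists matched on reads (percentile 100; central 95% of lists -0.60 to 0.82).

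Root marker mRNAs had a pooled ratio of 0.483 (0.348 to 0.665), with PYK10, a root beta-glucosidase, at 75.7 and 39 reads (ratio 0.566, 0.374 to 0.843), AHA2, a plasma membrane proton pump, at 29.5 and 6.5 (0.221, 0.0750 to 0.539), and PIP2-2 at 13.5 and 6. Housekeeping mRNAs had a pooled ratio of 0.742 (0.475 to 1.15), with UBQ10 at 23.5 and 21.8 reads, EF1A at 12.9 and 7.67 and ACT2 at 8 and 3. Green shoot markers had 15.5 and 17.8 reads in all, with a pooled ratio of 1.24 (0.597 to 2.60), LHCB2.1 at 10 and 4.5 reads, RBCS1A at 1.67 and 2 and CAB1 at 0.667 and 2.83. The 4 root markers and the 4 housekeeping genes with 5 or more reads had median log2 ratios of -0.92 (percentile 1.54) and -0.94 (percentile 1.33).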

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

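All tests in this part were chosen after the results were seen, and a biological response to low oxygen was not tested apart from library differences, since each condition had 1 library.

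The higher miRNA and TAS reads of the low-oxygen library coincide with its shift to shorter reads. A shorter size window in the low-oxygen library is argued against as the whole cause for 3 of the 14 called families, miR158, miR172 and miR5026, whose length-scaled interval lies above the largest ratio of another class over rRNA at their length (1.60 at 20 nt, 1.76 at 21 nt). It may account for 2, miR156 and miR408, whose length-scaled interval reaches or lies below 1 and stays within that spread (3 more, miR472, miR775 and miR837, reach 1 but extend beyond it); sense mRNA fragments of 18 to 20 and 25 to 27 nt differed from rRNA of the same length by a median of 0.17 on the log2 scale. For the other 9 families, and for the TAS loci with a pooled length-scaled ratio of 1.501 (1.427 to 1.579), the size window and other causes cannot be told apart, since their intervals do not lie above the spread between classes, though that of TAS2 alone (1.94 to 2.83) does. The 3 families miR158, miR172 and miR5026 are those with the largest ratios of the 14, and miR5026 rests on 4 control reads. The spread used is between pooled classes, and that between single sequences of a class was not weighed. At both lengths it is set by tRNA fragments, which include the CCA-ending reads described next (ratio 5.44 at 19 to 24 nt). The next class at 21 nt, reads between genes, had a ratio of 2.11, against 1.56 for rRNA. The split of the 14 families thus depends on the tRNA class, and a spread without it was not weighed. A difference between preparations other than length stays open.

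Fragments of 18 nt from tRNA 3′ ends with the added CCA, which the comparisons do not use, had a ratio of 9.07 (8.39 to 9.81), with 392 RPM in control and 3553 in low oxygen. A shorter size window could not give this alone, since 18-nt rRNA reads had a ratio of 2.90, other 18-nt tRNA reads 2.42 and 18-nt sense mRNA reads 3.43. Nor did 1 abundant fragment carry it: without the most abundant sequence the ratio was 9.52 (8.62 to 10.5), and all 15 tRNA isotypes with 20 or more reads had ratios above that of rRNA, 13 of them with an interval above it. A response of the roots and a difference in preparation that favours these ends may each still account for it.

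A 21-nt sequence 2 mismatches from miR168a-5p, with no genome match, had 1439 RPM in control and 2861 in low oxygen. Sequencing errors are argued against, since it reached 42.3% of miR168a-5p, while the largest other sequence at that distance reached 0.126% and that of miR166a-3p 0.0639%. It equals the form of miR168 known from cereals, as far as the cereal sequences used, which come from general knowledge and not from a database, are right. RNA of another plant may be its source, but 3 other cereal miRNA sequences summed to 1 read, so that source and others cannot be told apart.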

How the results depend on the processing

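Alternatives using length scaling or matched 20 to 24 nt reads were chosen after the data were seen. No paired analysis was possible because each condition had 1 library. Unless a value's construction shows it (a higher read minimum tests fewer items), the cause was not tested.

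Against 14 families higher and 1 lower, scaling to miRNA reads gave 9 and 4, length scaling 5 and 3, and hairpin reads 22 and 2. Hairpin reads covered more families, with a finite ratio above 0 for 56 with 20 or more reads, against 37. Their median ratio was 1.37, against 1.65. The 22 included 13 of the 14, without miR472, and the 2 did not include miR5653, the family called lower. Matched 20 to 24 nt reads gave 10 and 2, reads outside structural RNA 10 and 1, and a minimum of 100 reads 10 and 0. Scaling to matched 20 to 24 nt reads and to reads outside structural RNA both ended the higher calls of miR156, miR408, miR472 and miR837. All 9 families higher with miRNA reads and all 5 with length scaling were among the 14. miR156 reversed under length scaling, at 0.924.

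The pooled TAS ratio of 2.19 was 1.91 scaled to reads outside structural RNA, 2.06 with the trimmed mean, 1.87 with matched 20 to 24 nt reads, 1.501 length-scaled and 2.34 with 21 nt only, above 1 in each. Against 105 windows higher and 105 lower, a minimum of 100 reads gave 46 and 40, matched 20 to 24 nt reads 53 and 254, and length scaling 181 and 44. The hypoxia ratio of 6.04 was 10.3 with 20 to 24 nt reads only.

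Outside structural RNA, 21-nt reads made up 19.8% (control) and 24.5% (low oxygen), and 24-nt reads 30.2% and 24.9%. Without the 10 most abundant sequences these were 7.88% and 13.2%, and 21.8% and 19.3%. Over distinct sequences rRNA took 6.18% and 5.63%, and miRNA hairpins 0.229% and 0.246%. Over reads of 20 to 24 nt rRNA took 46.2% and 46.2%, and hairpins 13.3% and 14.2%. Among other named values, 84 moved within their interval and 71 beyond it. Of the 37 families, 13 without a size call, among them miR164 to miR168, changed side of 1 under length scaling, 8 when scaled to miRNA reads and 4 with matched 20 to 24 nt reads. Depth limits families and mRNAs under 20 reads.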

Other observations

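All items in this part were chosen after the data were seen. Reads of 20 to 24 nt on either strand of 282 genes annotated as PPR proteins, a family acting mainly on organelle RNA and targeted by miR161 and miR400, had a ratio of 1.88 (1.66 to 2.14) and a length-scaled ratio of 1.32 (1.16 to 1.51). Reads of 21 nt in them had 2.13 (1.82 to 2.49) and 1.37 (1.17 to 1.60) length-scaled. With each read divided over its genome matches, 89.3% of the 21-nt reads in these genes lay in 10 of them, led by AT1G62910 (chromosome 1, 23298948 to 23301141), with a ratio of 2.1 (1.43 to 3.13). Of the miR161 forms, miR161.2 had 20 and 119 reads, a ratio of 6.56 (4.06 to 11.1) and 4.21 length-scaled, and miR161.1 had 39 and 65, a ratio of 1.84 (1.22 to 2.81) and 1.18 length-scaled.

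Of 8854 genes with sense exon reads, 8 had 0 control reads and 7 or more low-oxygen reads, and 6 of these 8 were on the hypoxia list. The other 2 were AT3G43490 and MCCB, a subunit of methylcrotonyl-CoA carboxylase. In the other direction, 3 genes had 0 low-oxygen reads and 7 or more control reads, NUA, PAL1 and AT5G14650. These counts depend on the minimum of 7. AT1G02810, PDE345, EBF1 and AT3G17850, none on the hypoxia list, had 0 control and 6 low-oxygen reads. EXO70H5, CXIP4, GSTF10, AT4G10080, AGB1, sks9 and AT5G61310 had 6 control and 0 low-oxygen reads. Chloroplast fragments outside rRNA had a ratio of 1.496 (1.307 to 1.713), or 1.47 (1.29 to 1.69) length-scaled. Mitochondrial ones had 0.919 (0.872 to 0.969), which length scaling turned to 1.06 (1.002 to 1.113).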
